A study of Mus musculus with 4 samples.

How the data were processed

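Whole mouse testes of control and Wnk1-knockout (Wnk1_KO) males were dissociated and profiled by droplet single-cell RNA sequencing, with 2 libraries per genotype. Each library was made with a Chromium Single Cell 3′ kit from about 18000 live cells, per the labels' protocols; this kit tags the 3′ end of a transcript with a cell barcode and a unique molecular identifier (UMI). The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger on genome build mm10, per the submitters' processing notes. The notes name no Cell Ranger version, and they list R 4.0.2 and Seurat 4.0.0 with no role. The barcodes were those that Cell Ranger called as cells, and no cell annotation was used here. Every file held 32285 genes, and 32235 of them were given a chromosome from the GENCODE M21 annotation of the same build. The labels call the cells spermatocytes, although the source is whole testis and cells of every testis lineage were found.

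Barcodes with fewer than 500 genes, fewer than 1000 UMIs or over 20% mitochondrial UMIs were left out. Of 26093 barcodes, 22324 were kept after these filters and the doublet removal described next. Doublets were scored with the scrublet function of scanpy 1.11.5, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes. This removed 279 and 353 barcodes from control replicates 1 and 2, and 183 and 472 from Wnk1_KO replicates 1 and 2. Variable genes were chosen in groups of 2000, the libraries were aligned with the reciprocal-PCA anchors of Seurat 5.3.0 (10 anchor neighbours, 40 components), and cells were joined to 15 neighbours. Leiden clustering at resolution 1 with leidenalg 0.10.2 gave 42 clusters.

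Clusters were named from 16 marker lists fixed before the data were examined. A cluster took the list with the highest mean z-score over clusters, if that score reached 0.3 and at least 3 markers were detected. A cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed, as did one with a low median UMI count and no own marker among those genes. The rules for scores and leading genes were set after the clusters had been seen. The pachytene list and the diplotene and division list were merged into 1 class for the same reason, since clusters scored on both. Clusters 1, 3, 11, 16 and 36 stayed unnamed; the erythroid list named no cluster among kept cells. The class names are marker-based and every class is called "-like".

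Raw UMI counts were summed per library over all kept cells, and per library and class for the 6 classes with at least 50 cells in each of the 4 libraries. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) with Benjamini-Hochberg adjustment at 0.05 in each comparison. Levels are CPM (UMI counts scaled to a common library total) as mean ± SD of 2 libraries, and log2 fold changes are Wnk1_KO over control with their SE. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for 19 lists fixed before the data were examined plus X-linked and Y-linked genes, each with at least 5 tested members. Shares of cells and of X-linked counts were compared by a two-sided exact permutation test. With 2 libraries against 2 its smallest possible p is 0.333, so it cannot pass 0.05. Cells per class were also tested with edgeR, an alternative set beforehand. Intervals on a share in 1 library are exact binomial at 95%, cover counting error only, and the limit for a count of 0 is 3 cells. The p-values measure the spread between these 4 libraries. Control replicate 1 pooled 2 testes from 2 mice and the others held 1 testis each, per the labels, which do not say whether the single testes came from separate animals.

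RNA released by broken cells enters every droplet. Its share was estimated per class and library as the median ratio of tracer genes, which the class should not express, to their level in the whole library. For the late classes these were markers of differentiating spermatogonia and preleptotene spermatocytes. In pachytene-to-dividing cells of control replicates 1 and 2 they summed to 1636.0 and 1094.3 CPM, against 1333.3 and 881.8 CPM in the whole library. The class therefore did not lack all of them, which limits the estimate there. A gene was called a free-RNA gene in a class when the estimate set over 20% of its level there. This step was added after the data had been examined.

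Genes named in the text follow a rule fixed beforehand. For whole-library sums and the pachytene-to-dividing class it takes the 12 higher and 12 lower genes with the largest fold among those that passed, had at least 30 CPM and had both Wnk1_KO libraries on 1 side of both controls. Other classes give 6 per direction. Where no gene passed, the 3 higher and 3 lower genes with the smallest p are named and said not to pass, and each list gives up to 4 members with the smallest p. Predicted genes known only by a number were skipped in this naming.

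The tests were run on simulated counts drawn from the real means and library sizes with 200 changed genes. In the real sums over all cells 4912 genes were called. The adjustment depends on how many genes change, so the rates below need not hold for the real tests. In whole-library sums edgeR recovered 0% of 2-fold and 6% of 4-fold changes, against 8% and 51% with DESeq2 1.42.0. In differentiating spermatogonia it recovered 17% and 94%, in pachytene-to-dividing cells 4% and 58%, and in round spermatids 1% and 10%. DESeq2 made 22, 9, 15 and 10 false calls in these 4 comparisons and edgeR 0, 2, 0 and 0, so a longer list from DESeq2 holds more false calls as well. Alternatives covered scaling, the filter on low counts, DESeq2, a replicate block, each library left out, doublets, clustering resolution, classes transferred from control cells, cell filters, thinning to 2000 UMIs per cell, camera with an estimated correlation, and fry. Classes under 50 cells in a library were left out of gene tests, and no ratio of spliced to unspliced reads could be formed from these counts.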

Results

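Single-cell transcriptomes of whole testes were compared between control and Wnk1_KO males of C57BL/6J mice over 5 weeks old, an age at which the seminiferous tubules hold germ cells from spermatogonia to spermatids. WNK1 is a kinase that controls cation-chloride cotransport through its substrates OXSR1 and STK39, and the series concerns its part in the completion of meiosis. There were 2 control and 2 Wnk1_KO libraries. The files held 139133890 UMIs in control replicate 1, 87638441 in control replicate 2, 70239883 in Wnk1_KO replicate 1 and 108501108 in Wnk1_KO replicate 2. After filtering, 5597, 6058, 4218 and 6451 cells remained in the same order, with medians of 9747, 5546.5, 9083 and 11251 UMIs per cell.

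Wnk1 itself (ENSMUSG00000045962; mm10 chromosome 6, 119923969 to 120038672, minus strand) was detected in every library. Over all kept cells its level was 32 and 53.9 CPM in control replicates 1 and 2, and 57.6 and 118 CPM in Wnk1_KO replicates 1 and 2, from 3819 to 11656 UMIs. The log2 fold was 0.51 and did not pass (edgeR, adjusted p = 0.451); it was 0.00 without Wnk1_KO replicate 2 and 1.06 without Wnk1_KO replicate 1. In leptotene and zygotene spermatocyte-like cells, where the gene was highest, the 2 control libraries held 318 and 485 CPM and the 2 Wnk1_KO libraries 224 and 343 CPM, a log2 fold of -0.49. The fold was -0.47 in differentiating spermatogonia-like, -0.44 in preleptotene-like and -0.77 in pachytene-to-dividing spermatocyte-like cells (edgeR, adjusted p = 0.331 in the last). It was 0.88 in round and 0.21 in elongating spermatid-like cells, and none of the 6 classes passed without a replicate block. Single libraries moved these folds: without control replicate 2 they were -0.11 in leptotene and zygotene-like, -0.16 in preleptotene-like and -0.31 in differentiating spermatogonia-like cells, and without Wnk1_KO replicate 1 -0.35 in pachytene-to-dividing cells. Without control replicate 1 they were -0.71 in differentiating spermatogonia-like and -0.72 in preleptotene-like cells. Without Wnk1_KO replicate 2 they were -0.86 in leptotene and zygotene-like and -1.37 in pachytene-to-dividing cells, and turned to -1.93 in round and -0.52 in elongating cells. From differentiating spermatogonia-like to pachytene-to-dividing cells, each Wnk1_KO library lay below the same-numbered control. Wnk1 passed in these classes with a replicate block, which the labels tie to no batch and which is described with the processing below. The labels do not name the deleted exons, and a 3′ tag outside the deleted part checks nothing, so these counts neither bear out nor contradict the genotype labels.

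The question of whether germ cells completed meiosis was read from the make-up of the tissue. Post-meiotic cells, meaning round and elongating spermatid-like cells, made up 56.9% ± 17.5 (SD, n = 2) of the germ cells in control and 11.1% ± 4.32 (SD, n = 2) in Wnk1_KO libraries. The share was 44.5% (95% interval 43.0 to 46.0) and 69.3% (68.0 to 70.6) in control replicates 1 and 2, and 8.01% (7.05 to 9.04) and 14.1% (13.2 to 15.1) in Wnk1_KO replicates 1 and 2. The log2 ratio was -2.36, and both Wnk1_KO libraries lay below both controls. The exact permutation p was 0.33, the smallest this design allows, and edgeR on cells per class gave an adjusted p of 0.0114. Depth differed between the classes compared: control round spermatid-like cells had medians of 7018 and 4070 UMIs, and Wnk1_KO ones 14988 and 3348.

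The classes before pachytene took a larger part of the Wnk1_KO libraries. Differentiating spermatogonia-like cells, the mitotic cells that lead into meiosis, rose from 4.81% ± 0.131 to 27.3% ± 3.25 of all kept cells (SD, n = 2 each; log2 ratio 2.51; edgeR adjusted p = 0.0161). Preleptotene-like spermatocytes, which replicate DNA before meiosis, rose from 2.66% ± 0.586 to 13.1% ± 1.09 (edgeR adjusted p = 0.0161). Leptotene and zygotene-like spermatocytes, in which homologous chromosomes pair, rose from 2.4% ± 0.242 to 11.3% ± 0.979, and undifferentiated spermatogonia-like cells from 0.708% ± 0.142 to 2.24% ± 0.318 (edgeR adjusted p = 0.0161 and 0.0396). Elongating spermatid-like cells fell from 23.7% ± 8.24 to 3.37% ± 0.579 (log2 ratio -2.81; edgeR adjusted p = 0.0161).

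Pachytene-to-dividing spermatocyte-like cells made up 23.4% ± 12.5 in control and 12% ± 4.01 in Wnk1_KO libraries (SD, n = 2 each), with overlapping libraries and no pass (edgeR adjusted p = 0.191). Without control replicate 1 their log2 ratio was -0.28 in place of -0.97. Round spermatid-like cells were at 21.9% ± 7.53 and 4.97% ± 3.24, a log2 ratio of -2.14 that missed the threshold (edgeR adjusted p = 0.0551). Without Wnk1_KO replicate 2 that ratio was -3.03, and without Wnk1_KO replicate 1 it was -1.60. The exact permutation test adjusted over classes gave 0.454 or more for each class. A share is a part of a fixed total, so a lower share of late cells raises the share of all others; the labels give no cell number per testis.

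Cells outside the germ line were fewer. Sertoli-like cells, which nurse the germ cells, were at 2.16% ± 0.533 and 2.31% ± 2.46 (SD, n = 2 each), but the Wnk1_KO libraries held 4.05% and 0.574%; without Wnk1_KO replicate 1 the log2 ratio was -1.91 in place of 0.10. Interstitial stroma-like cells were at 0.849% ± 0.0132 and 3.12% ± 3.36, and their log2 ratio of 1.88 became -0.19 without Wnk1_KO replicate 1. Macrophage-like cells were at 0.565% ± 0.0412 and 1.43% ± 0.556 (edgeR adjusted p = 0.0792), with a log2 ratio of 0.88 without Wnk1_KO replicate 1. T and NK lymphocyte-like cells passed in edgeR (adjusted p = 0.0191) on only 31 cells: 0 of 5597 and 1 of 6058 in control, and 18 of 4218 and 12 of 6451 in Wnk1_KO libraries. The 0 allows a share of up to 0.0536%. Leydig-like (62 cells), endothelial-like (49 cells) and peritubular myoid-like cells (34 cells) did not pass (edgeR adjusted p = 0.0987, 0.0551 and 0.0987).

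Unnamed clusters held 16.5% ± 2.58 of control and 17.2% ± 2.15 of Wnk1_KO cells (SD, n = 2 each). Cluster 1, which scored highest on the preleptotene list, took 2.29% and 2.13% of control replicates 1 and 2 but 9.41% and 10.7% of Wnk1_KO replicates 1 and 2. Cluster 3, nearest to the pachytene lists, took 3.09%, 9.01%, 1.66% and 4.79% in that order. Clusters 11 and 16, nearest to round spermatids, took 6.95% and 6.04% of control replicate 1 and between 0.791% and 2.73% of the other libraries, and cluster 36 took 0%, 0%, 0.237% and 0.961%. Clusters 1, 11 and 16 were then added to the germ-cell total, with clusters 11 and 16 as post-meiotic cells. Clusters 3 and 36 scored under 0.3 on every list and were left out. The post-meiotic share was 60.1% ± 12.5 in control and 13.3% ± 1.92 in Wnk1_KO libraries (SD, n = 2 each).

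**Figure D1:**
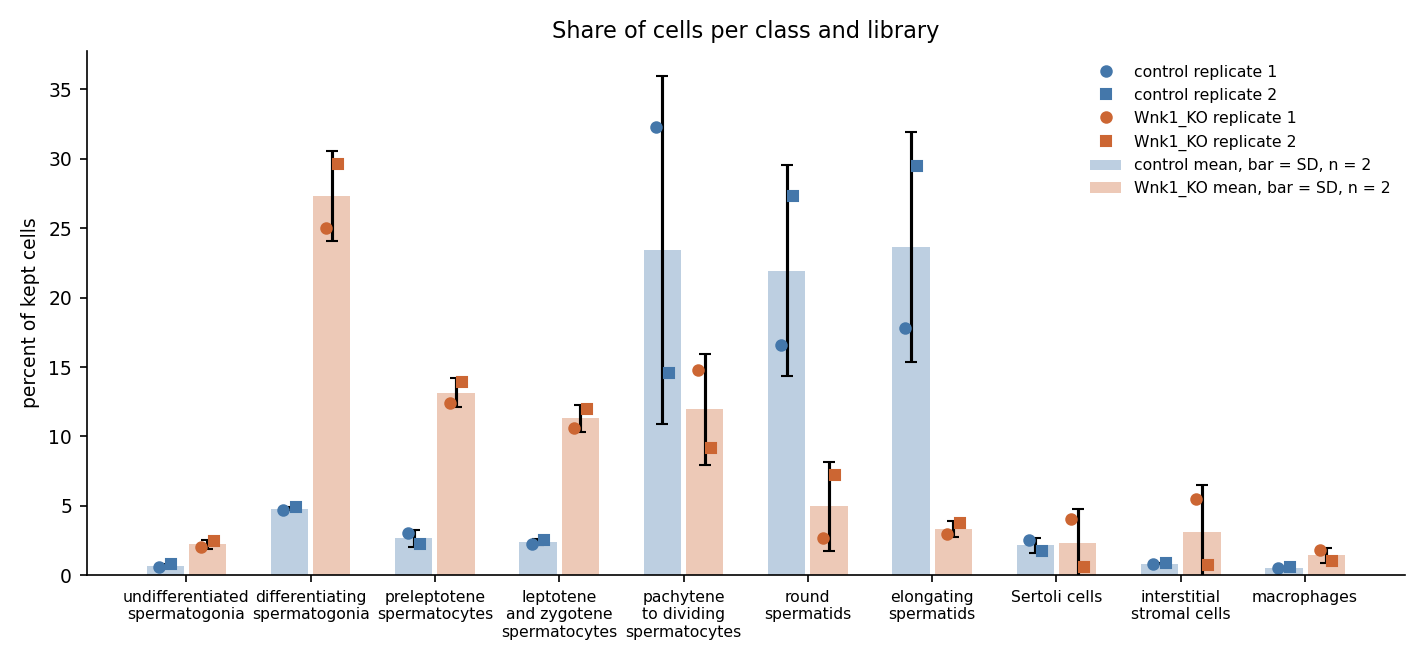
Share of kept cells per marker-named class (percent, axis from 0) in each of the 2 control and 2 Wnk1_KO libraries, with points for libraries and bars for group means ± SD. Differentiating spermatogonia-like cells were at 4.81% and 27.3%, and elongating spermatid-like cells at 23.7% and 3.37%.

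The sums over all cells of a library moved with this make-up. Among the genes that rose in Wnk1_KO libraries, Stra8, the retinoic-acid-induced switch into meiosis, went from 44.8 ± 22.6 to 229 ± 96.3 CPM (SD, n = 2 each; log2 fold 2.36 ± 0.53 SE; edgeR adjusted p = 0.0255). Tex12, a part of the synaptonemal complex, went from 38.3 ± 11.9 to 188 ± 13.2 CPM, and Ccne2, a cyclin of S-phase entry, from 14.1 ± 3.25 to 76.3 ± 1.68 CPM. Among those that fell, Tssk6, a kinase needed for sperm chromatin condensation (ENSMUSG00000047654; chromosome 8, 69902184 to 69903518), went from 1390 ± 1370 to 85.4 ± 16.6 CPM, and Prm2, a protamine that replaces histones, from 25400 to 2150 CPM (log2 fold -3.57 ± 0.69 SE; edgeR adjusted p = 0.0222). Of 21832 genes tested, 1659 rose and 3253 fell (edgeR; 10115 at an unadjusted p under 0.05). DESeq2 called 3994 higher and 4665 lower.

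The genes with the largest rise also included Lsm3 (ENSMUSG00000034192; chromosome 6, 91515928 to 91522625), a core part of the RNA-splicing and decay LSM ring, from 52.3 ± 18.4 to 358 ± 53 CPM, and Chchd4 (ENSMUSG00000034203; chromosome 6, 91462172 to 91473546), which imports proteins into the mitochondrial intermembrane space, from 22.8 ± 2.98 to 152 ± 1.9 CPM (SD, n = 2 each). Rnaset2a, Hccs, Ptma, Hprt, Crabp1, Wdr43 and Rbp4 complete the 12, with log2 folds between 2.21 and 2.51 and edgeR adjusted p between 0.0222 and 0.0422. Rnaset2a has a near-identical copy, so its counts are uncertain. The largest falls besides Tssk6 were Acte1, Itpr3os, Prkar2a, Car2, Tppp2, Ppp2r2b, Pldi, Ttc24, Arl9, Nudt16l2 and Lrrc57, with log2 folds from -3.57 to -4.07 and an edgeR adjusted p of 0.0222 each. Itpr3os overlaps its antisense partner, and the controls differed widely for several of these genes, as for Prkar2a at 403 ± 403 CPM.

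The count of changed genes depended on single libraries. From 4912, it was 2847 without control replicate 1, 7975 without control replicate 2 and 613 without Wnk1_KO replicate 2. Of the 24 named genes, 19, 24 and 21 were still called in these 3 fits, none with another sign.

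Of 4 lists of meiotic genes camera called 3 higher over all cells, and it called 3 lists of sperm parts lower; meiotic division was not called (adjusted p = 0.212). Every one of these calls was lost, at an adjusted p = 0.635 with an estimated correlation. With 4 libraries that setting has little power, and it ended all 51 list calls of camera in these data. A loss under it therefore does not tell a weak list from a strong list, here or below. In the synaptonemal complex and cohesin list 4 of 18 members rose and 14 did not pass (6 adjusted over the list alone), led by Tex12, Sycp3 (132 to 427 CPM) and Terb2. In meiotic recombination 5 of 29 rose and 24 did not pass (5 adjusted over the list alone), among them Dmc1 (10.5 to 46.7 CPM), the meiotic strand-exchange recombinase, and Prdm9. Of 15 sex body and silencing factors 0 passed over all genes and 0 adjusted over the list alone, H2afx being at a log2 fold of 1.24 (edgeR adjusted p = 0.0551). Of 20 acrosome and fusion genes 14 fell (18 adjusted over the list alone), with Izumo1, the sperm ligand of the egg, from 124 to 23.2 CPM and Spam1 from 123 to 23.7 CPM. Of 16 chromatin condensation genes 11 fell (12 lower and 1 higher adjusted over the list alone), and of 33 flagellum genes 18 fell (22 adjusted over the list alone), with Catsper3 from 179 to 33.0 CPM.

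Camera called these lists, with adjusted p of 0.0137, 0.00333 and 0.00309 for the 3 meiotic lists, and 1.94e-08, 0.000357 and 6.53e-08 for the 3 lists of sperm parts. It also called CCR4-NOT and mRNA decay higher (6 of 32 rose, 5 adjusted over the list alone, led by Btg3; 0.00399), mTOR signalling (5 of 25 rose and 1 fell, 6 and 1 adjusted over the list alone; Rheb from 56.6 to 206 CPM, Eif4e from 515 to 160 CPM; 0.00119) and p53 and apoptosis (9 of 27 rose, 12 higher and 1 lower adjusted over the list alone; Trp53 from 7.22 to 23.2 CPM; 0.00309). Immediate early genes (2 of 17 rose, 0 adjusted over the list alone; 0.0466) and X-linked genes (104 of 790 rose and 12 fell, 0 adjusted over the list alone; 7.23e-07) were called higher too. The 5 further calls were lost in the same way, at an adjusted p = 0.635 with an estimated correlation. Marker genes of early germ cells and spermatids moved with the cell shares beside each of these lists.

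The other lists were not called by camera over all cells. Meiotic division had 7 of 30 members higher, such as Ccna2 and Sgo1, and 7 adjusted over the list alone. Among 21 spermatogenic transcription regulators (0.605) 4 rose and 2 fell, with 6 and 4 adjusted over the list alone; their median log2 fold was -0.05 and their mean 0.22. Of 19 piRNA factors (0.655) Gtsf1 fell, from 1090 to 406 CPM, and 0 adjusted over the list alone. The integrated stress response (0.179) had 2 of 19 higher and 3 lower, with 4 and 3 adjusted over the list alone, and Slc7a11 and Herpud1 among the lower. Heat shock (0.909) had 1 of 20 higher and 3 lower by both counts over all genes and adjusted over the list alone. Testis metabolism (0.179) had 5 of 23 higher and 5 lower, with 6 and 11 adjusted over the list alone; Aldoart1, a sperm glycolytic enzyme, went from 90.7 to 8.02 CPM. Sertoli genes (0.321) had 1 of 19 higher and 2 lower by both counts over all genes and adjusted over the list alone, steroidogenesis (0.145) had 1 of 16 higher and 0 adjusted over the list alone, and Y-linked genes (0.336) had 1 of 105 higher and 1 lower and 0 adjusted over the list alone. In the WNK pathway list (0.723) 0 of 16 passed over all genes or adjusted over the list alone; Oxsr1 went from 7.35 to 28.7 CPM (log2 fold 1.97 ± 0.63 SE; edgeR adjusted p = 0.0525) and Slc12a2 from 9.68 to 30 CPM.

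Within spermatogonia and early spermatocytes, few genes rose and many spermatid genes fell. In differentiating spermatogonia-like cells Lsm3 went from 396 ± 47.5 to 853 ± 218 CPM (SD, n = 2 each; log2 fold 1.11 ± 0.25 SE; edgeR adjusted p = 0.0317), and Xpc, a DNA damage sensor, from 33 ± 3.61 to 69.2 ± 5.81 CPM. Prm2 went from 903 ± 35.8 to 118 ± 41.7 CPM, and Myl10, Iqcf3, Tex22, Eid3 and Krt88 fell by log2 folds of -2.75 to -3.09. In all, 4 of 14556 genes rose and 1754 fell (edgeR; DESeq2 called 11 and 1679). Of the 1754, 1750 were free-RNA genes. For these, RNA released by other cells was estimated to set over 20% of the level in at least 1 group. Without free-RNA genes, a choice made after the data were examined, edgeR called 0 genes here (194 at an unadjusted p under 0.05; DESeq2 called 0 higher and 1 lower) and 0 in each of the 5 other classes. Lsm3 and Xpc were not free-RNA genes and kept log2 folds of 0.93 ± 0.23 SE and 0.91 ± 0.21 SE, yet their edgeR adjusted p was 1 each. With the p of the first fit adjusted over the genes left, it was 0.978 for both, so they passed only beside the many free-RNA genes.

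In preleptotene-like spermatocytes 11 of 11175 genes rose and 1395 fell (edgeR; DESeq2 called 10 and 1267), and all 1395 were free-RNA genes. The rises included Tubb5, a tubulin (18.7 ± 2.15 to 52.7 ± 8.87 CPM), Chchd4 (216 ± 92.6 to 601 ± 240 CPM), Gal, the neuropeptide galanin, and Lsm3, with log2 folds of 1.5, 1.47, 1.39 and 1.00 and edgeR adjusted p from 0.019 to 0.0472. Fyb, Tex22, Myl10, Spert, Ccdc7a and Prm2 fell, with log2 folds from -2.96 to -3.10. In leptotene and zygotene-like spermatocytes 21 of 10606 genes rose and 1570 fell (edgeR; DESeq2 called 21 and 1299), 1566 of the latter being free-RNA genes. Stra8 went from 132 ± 33.6 to 302 ± 9.96 CPM (log2 fold 1.20 ± 0.27 SE; edgeR adjusted p = 0.0205) and H2afx, the histone that marks DNA breaks and the sex body, from 128 ± 17.8 to 259 ± 43.9 CPM (log2 fold 1.02). Zglp1 and Figla, regulators known from the oogenic programme, rose with log2 folds of 1.58 and 1.42, as did Chchd4 (1.57) and the spindle gene Ckap2 (1.27). As with Lsm3 and Xpc above, no gene in these 2 classes passed when free-RNA genes were left out: Stra8 kept a log2 fold of 1.00 ± 0.30 SE and Chchd4 1.37 ± 0.36 SE in leptotene and zygotene-like cells (edgeR adjusted p = 0.999 each). Prkg1, Cylc2, Otub2, Ccdc175, Fyb and AI507597 fell, with log2 folds from -3.25 to -3.82.

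The gene lists in these 3 classes followed the spermatid genes. Camera called acrosome, chromatin condensation, flagellum and testis metabolism genes lower in each of the 3. These 12 calls were lost with an estimated correlation, at adjusted p from 0.131 (flagellum in preleptotene-like cells) to 0.545. Most members of these lists were free-RNA genes (in differentiating spermatogonia-like cells 20 of 20, 13 of 16, 32 of 33 and 15 of 23), so without free-RNA genes 8 of the 12 calls had too few members left to test. Of the others, chromatin condensation in leptotene and zygotene-like cells was not called (camera adjusted p = 0.751), and metabolism turned higher without passing in each class (0.919, 0.834 and 0.268). Of 20 acrosome genes 20, 19 and 20 fell in the order of the classes (20 in each adjusted over the list alone), and of the flagellum genes 27 of 33, 27 of 33 and 26 of 31 (30 in each adjusted over the list alone). Chromatin condensation had 11, 11 and 10 of 16 lower (11 in each adjusted over the list alone). Metabolism had 9 of 23, 10 of 22 and 9 of 22 lower, with 12, 13 and 10 lower and 0, 0 and 1 higher adjusted over the list alone. Camera called mTOR signalling higher in differentiating spermatogonia-like (adjusted p = 0.0237) and leptotene and zygotene-like cells (0.0322), CCR4-NOT in preleptotene-like (0.0358) and leptotene and zygotene-like cells (0.0149), and X-linked genes in the same classes (0.0127 and 0.00126). These 6 calls were lost with an estimated correlation as well, and only X-linked genes in leptotene and zygotene-like cells kept theirs without free-RNA genes (0.000376). In the mTOR and CCR4-NOT lists no member passed over all genes or adjusted over the list alone. X-linked genes had 1 higher and 10 lower of 413 in preleptotene-like cells and 1 and 15 of 393 in leptotene and zygotene-like cells, with 0 higher and 2 and 1 lower adjusted over the list alone. In differentiating spermatogonia-like cells X-linked genes were not called, with a median log2 fold of 0.14 and a mean of -0.05. The WNK pathway list was not called in any (camera adjusted p = 0.508, 0.783 and 0.948), and 0, 1 and 1 of its members fell, the same numbers adjusted over the list alone. The member was Stk39, the kinase WNK1 activates, from 60.2 to 22.3 and from 68.3 to 15.9 CPM, and a free-RNA gene in both. Without control replicate 2, camera called 10 lists in preleptotene-like cells in place of 6.

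Along the chromosomes, 5 genes on chromosome 6 (91440987 to 91522625), neighbours among the 8400 genes tested in all 6 classes, were higher in both Wnk1_KO libraries in each of these classes, a run chosen after its values were seen. They are 1810044D09Rik, Chchd4, Tmem43, Xpc and Lsm3, and they passed in 1, 3, 2, 3 and 3 of the 6 classes. Over all cells their log2 folds were 0.37 (edgeR adjusted p = 0.489), 2.74, 3.19, 2.59 and 2.78. No other run of genes with log2 folds over 0.5 and 1 sign in all 6 classes was longer than 2 genes. The run lies 28.4 Mb from Wnk1. The next genes on its sides, Iqsec1 and Slc6a6, had class log2 folds of -0.04 to 0.42 and -2.67 to 0.13.

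**Figure D2:**
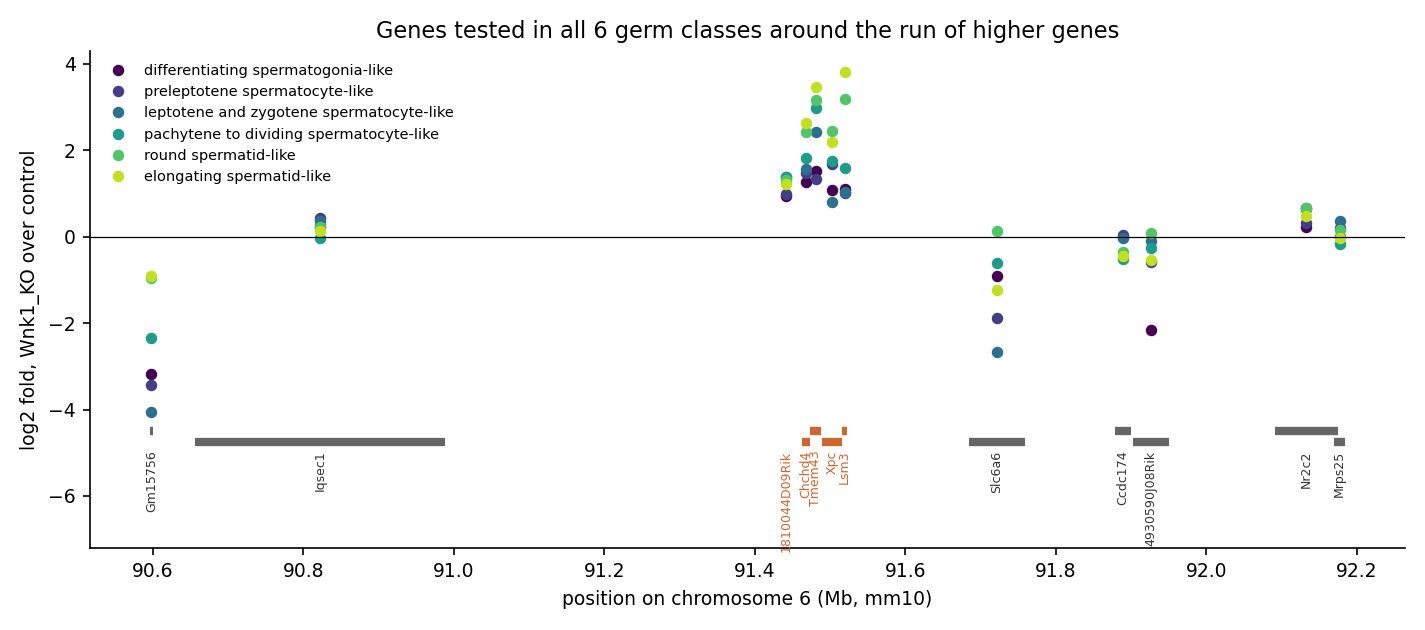
Log2 fold change of Wnk1_KO over control for the genes around 91 Mb on chromosome 6 (position in Mb on the horizontal axis) in the 6 classes tested, 1 point per gene and class. The 5 genes from 91440987 to 91522625 lie above 0 in every class, between 0.79 and 3.8.

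The pachytene-to-dividing class was the main class for the question of meiosis, and no gene in it passed. The smallest p values belonged to Cldn5, a claudin of tight junctions (2.62 ± 0.411 to 86.1 ± 14.1 CPM; SD, n = 2 each; log2 fold 5.05 ± 0.34 SE), the homeobox gene En2 (0.538 ± 0.0909 to 18 ± 2.29 CPM) and Tagln2, an actin-binding protein (3.21 ± 0.232 to 70.5 ± 26.6 CPM), each at an edgeR adjusted p of 0.0714. Lower, and not passing either, were Nudt12os (16.1 ± 3.3 to 0.322 ± 0.0842 CPM), Gucy2d (6.09 ± 0.186 to 0.211 ± 0.00134 CPM) and Prm2 (880 ± 131 to 93.6 ± 32.3 CPM), the last 2 being free-RNA genes in this class. edgeR called 0 of 15720 genes, with 3654 at an unadjusted p under 0.05 (1781 higher, 1873 lower), and DESeq2 called 651 higher and 840 lower. With 1 library left out edgeR called 1289 genes without control replicate 1, 1044 without control replicate 2, 798 without Wnk1_KO replicate 1 and 819 without Wnk1_KO replicate 2.

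This class differed in depth and in its clusters between libraries. Its median was 32527 UMIs per cell in control replicate 1 and 4509 in control replicate 2, against 40995 and 36277.5 in Wnk1_KO replicates 1 and 2. Cluster 4 was the largest in both control libraries (581 of 1808 and 372 of 883 cells), and clusters 13 and 7 the largest in Wnk1_KO libraries (189 and 159 of 625 in replicate 1, 103 and 194 of 590 in replicate 2). Cluster 4 had a median of 5586.5 UMIs per cell, and clusters 13 and 7 had 45596.0 and 48070.5. A shift in stage therefore cannot be told from one in depth here.

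Sex-linked genes stood higher in this class as a group. Of 510 X-linked genes 448 had a positive log2 fold, with a median of 0.85; 0 passed over all genes, and 115 higher and 8 lower adjusted over the list alone. Of 77 Y-linked genes 73 were positive, with a median of 1.10, and 0 passed by either count, adjusted over the list alone included. Camera called both higher (adjusted p = 5.56e-20 and 1.71e-09), and both calls were lost at an adjusted p = 0.489 with an estimated correlation. It also called the synaptonemal complex (0.0384; 4 higher adjusted over the list alone; Sycp2 from 75.5 to 138 CPM), recombination (0.0453; 0 adjusted over the list alone; Hfm1 from 2.67 to 10.1 CPM), sex body (0.0443; 0 adjusted over the list alone; Hormad1 from 60.9 to 105 CPM) and p53 lists higher (0.0181; 2 adjusted over the list alone; Pmaip1, a pro-apoptotic p53 target, from 0.148 to 2.35 CPM). Acrosome (0.000515; 1 lower adjusted over the list alone), chromatin condensation (4.35e-07; 7 lower adjusted over the list alone) and flagellum genes (0.0349; 0 adjusted over the list alone) were called lower. These 7 calls were lost in the same way, at the same value, and in the 7 lists 0 members passed over all genes. Without free-RNA genes acrosome (0.00366), p53 (0.0119), X-linked and Y-linked genes were still called, while the synaptonemal, recombination, sex body and flagellum lists were not (0.186, 0.536, 0.0771 and 0.186) and chromatin condensation had too few members left to test. Without Wnk1_KO replicate 2 only 5 lists were called. The WNK pathway list was not called (camera adjusted p = 0.464; 0 over all genes, 1 adjusted over the list alone).

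In round spermatid-like cells no gene passed. The smallest p values belonged to Cldn5 (0.923 ± 0.0324 to 23.4 ± 0.701 CPM; SD, n = 2 each), the stress gene Gadd45b (1.78 ± 0.696 to 39.4 ± 0.349 CPM) and Actr3b (0.206 ± 0.11 to 10.4 ± 0.428 CPM) among the higher, and Nnmt (25.7 ± 8.65 to 0.186 ± 0.264 CPM), Mucl1 and the polarity gene Patj (70 ± 4.69 to 12.7 ± 4.84 CPM) among the lower, each at an edgeR adjusted p of 0.27. Cldn5, Gadd45b, Actr3b and Mucl1 were free-RNA genes here. edgeR called 0 of 14512 genes, with 1751 at an unadjusted p under 0.05 (1217 higher, 534 lower), and DESeq2 called 77 higher and 25 lower. Without control replicate 1 or control replicate 2 edgeR called 13 genes each.

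Camera called 6 lists higher in round spermatid-like cells. Of 453 X-linked genes 414 were positive, with a median log2 fold of 1.08 (adjusted p = 1.76e-22), and of 72 Y-linked genes 69, with a median of 1.39 (7.84e-12); 0 passed over all genes and 0 adjusted over the list alone in both. The p53 list was called (0.000145; 0 of 14 over all genes, 6 adjusted over the list alone), with Cdkn1a, the p53-induced cell cycle inhibitor, from 10.8 to 49.4 CPM and Casp9 from 1.51 to 7.08 CPM. The synaptonemal complex (0.0432; 0 over all genes, 2 adjusted over the list alone), sex body (0.0171; 0 by both counts, adjusted over the list alone included) and mTOR lists (0.0171; likewise 0) were called as well. Of the p53 list 8 of 14 members were free-RNA genes, and without them its adjusted p was 0.887; of the synaptonemal, sex body and mTOR lists 14 of 17, 14 of 15 and 17 of 20 were, too many to test the rest. The X-linked and Y-linked calls were kept (2.43e-32 and 4.83e-24). All 6 calls were lost: adjusted p = 0.208 with an estimated correlation for X-linked genes, 0.662 for the sex body and 0.556 for the other 4. Cluster 2 held 268 and 731 of the control cells of this class, while 61 of 113 cells of Wnk1_KO replicate 1 were in cluster 26 and 150 of 468 cells of Wnk1_KO replicate 2 in cluster 23. Without Wnk1_KO replicate 2 only 3 lists were called.

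In elongating spermatid-like cells genes moved both ways. Hmgb2, a chromatin protein of dividing cells, went from 3.45 ± 0.481 to 59.5 ± 10.9 CPM (SD, n = 2 each; log2 fold 4.11 ± 0.39 SE; edgeR adjusted p = 0.0148), and Ptma and Cirbp rose with log2 folds of 3.90 and 2.85; all 3 were free-RNA genes. Nptx2, a neuronal pentraxin (4.4 ± 0.675 to 56.5 ± 24.3 CPM), the iron-siderophore carrier Lcn2 (6.04 ± 0.092 to 56.2 ± 8.32 CPM) and Serp2 (21.8 ± 3.8 to 131 ± 44.4 CPM) rose with free-RNA estimates of 10.2%, 4.85% and 7.85% of their level. Gucy2d went from 53.8 ± 21.5 to 9.94 ± 2.62 CPM (estimate 3.49%), while Lrrc34, Prkg1, Zpbp2, Acyp1 and Tmbim7 fell as free-RNA genes with log2 folds from -2.37 to -2.83. Of 12774 genes, 1238 rose and 460 fell (edgeR; DESeq2 called 944 and 533), and 1048 and 327 of these were free-RNA genes. The count of 1698 was 1126 without control replicate 2 and 729 without Wnk1_KO replicate 2; it was 134 with cells thinned to 2000 UMIs, and edgeR called 0 at Leiden resolution 2 (3134 at an unadjusted p under 0.05; DESeq2 called 539 higher and 198 lower) and 0 without free-RNA genes (989; DESeq2 called 143 and 84).

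Camera called 7 lists in this class. X-linked genes were higher (116 of 385 rose and 1 fell, 161 and 3 adjusted over the list alone; adjusted p = 7.84e-15, and adjusted p = 0.352 with an estimated correlation). The synaptonemal complex (5 of 17 rose, 6 adjusted over the list alone; 0.00899), sex body (3 of 13, 6 adjusted over the list alone; 0.00619), CCR4-NOT (6 of 29, 6 adjusted over the list alone; 0.0197) and mTOR lists (6 of 21, 6 adjusted over the list alone; 0.00777) were higher, led by Tex12, Scml2, Btg3 and Akt1. Of their members 14 of 17, 12 of 13, 24 of 29 and 14 of 21 were free-RNA genes; without these CCR4-NOT and mTOR were at 0.868 and 0.26 and the first 2 had too few members left to test. Without Wnk1_KO replicate 2 the synaptonemal, sex body and CCR4-NOT calls were lost (0.118 each). Acrosome (2 of 20 fell, 2 adjusted over the list alone; 0.000754) and flagellum genes (5 of 33 fell, 9 adjusted over the list alone; 0.000754) were lower, led by Zpbp2 and Tekt4; without free-RNA genes flagellum was at 0.66 and acrosome had too few members left, so that only X-linked genes were still called (3.03e-17). Those 6 calls were lost too, at an adjusted p = 0.534 with an estimated correlation for mTOR and flagellum genes and 0.703 for the others. Cluster 15 held 55 of 125 and 85 of 244 Wnk1_KO cells of this class, while clusters 18 and 14 held the most control cells, 250 of 999 in replicate 1 and 474 of 1787 in replicate 2.

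The X chromosome is silenced in pachytene spermatocytes and stays largely silent in round spermatids. X-linked genes took 0.685% ± 0.228 of the nuclear-gene counts in control pachytene-to-dividing spermatocyte-like cells and 1.09% ± 0.18 in Wnk1_KO ones (SD, n = 2 each; log2 ratio 0.67). The share was 1.64% ± 0.00883 and 3.38% ± 0.382 in round spermatid-like cells (log2 ratio 1.04), and 1.4% ± 0.0753 and 3.07% ± 0.182 in elongating ones (log2 ratio 1.13). Both Wnk1_KO libraries lay above both controls in each class. The log2 ratio was 0.12 in differentiating spermatogonia-like, 0.18 in preleptotene-like and 0.26 in leptotene and zygotene-like cells, and 0.10 in undifferentiated spermatogonia-like cells. It was 0.93 in Sertoli-like, 0.46 in macrophage-like and 0.34 in stroma-like cells. The exact permutation p was 0.33 for each of these X-linked shares, adjusted to 0.416. Without control replicate 1 the ratio in the pachytene-to-dividing class was 0.37, and without control replicate 2 it was 1.06.

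Y-linked shares were higher in both Wnk1_KO libraries than in both controls in the late classes and, by less, in the 3 early ones. They were 0.0635% ± 0.00802 and 0.124% ± 0.0316 in pachytene-to-dividing spermatocyte-like cells, 0.0803% ± 0.00599 and 0.192% ± 0.0281 in round and 0.0188% ± 0.00633 and 0.038% ± 0.0103 in elongating spermatid-like cells (SD, n = 2 each), log2 ratios of 0.97, 1.26 and 1.01. The log2 ratios were 0.31 in differentiating spermatogonia-like, 0.26 in preleptotene-like and 0.42 in leptotene and zygotene-like cells. With each library left out in turn these 3 ratios ranged from 0.18 to 0.42, 0.14 to 0.38 and 0.25 to 0.61. Against the change in differentiating spermatogonia-like cells, X-linked genes rose more by a median log2 difference of 1.14, 1.11 and 1.12 in these 3 classes, while all genes moved by 0.09, 0.14 and 0.13. Y-linked genes differed by 1.59, 1.66 and 0.55. The test of this difference, an edgeR fit with each library as a block followed by camera, gave adjusted p of 4.03e-10, 1.15e-07 and 1.89e-07 for X-linked genes. Y-linked genes were called in the first 2 of these classes (5.92e-05 each) and not in elongating spermatid-like cells (0.284). With an estimated correlation the adjusted p = 0.215, 0.0777 and 0.0777 for X-linked and 0.215, 0.215 and 0.417 for Y-linked genes.

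**Figure D3:**
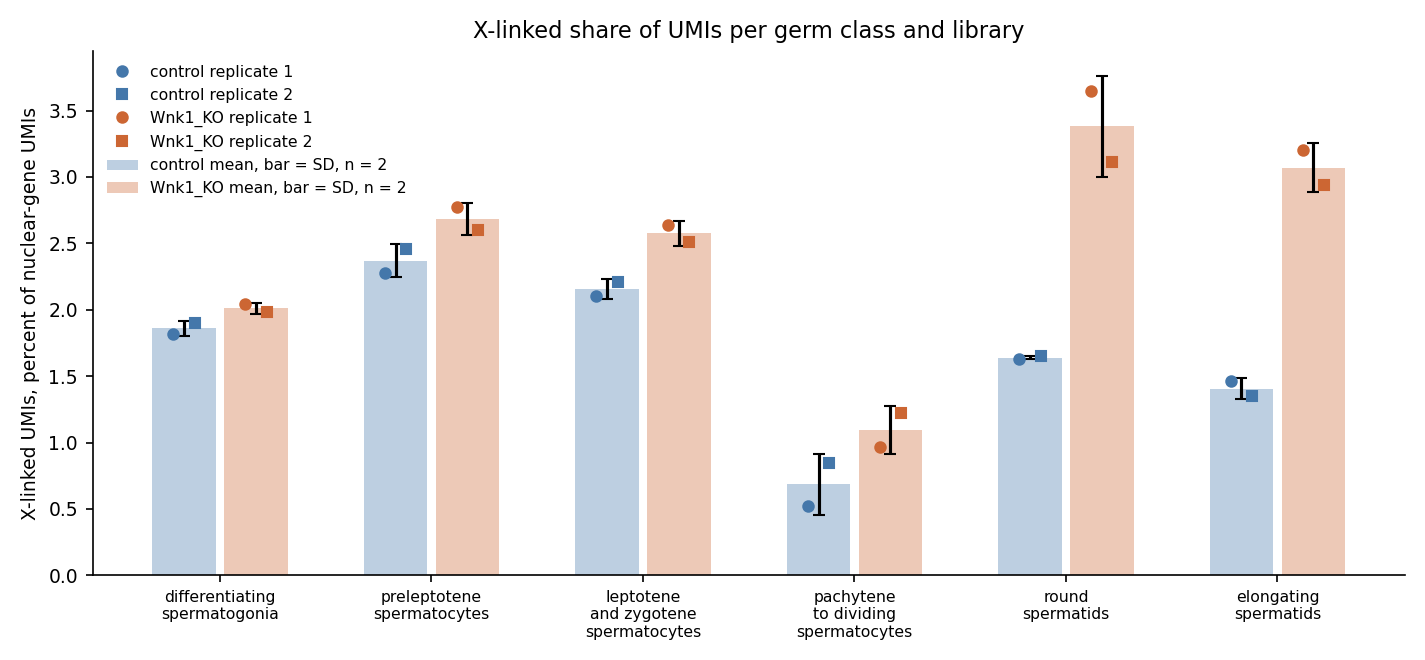
Share of X-linked counts (percent of UMIs of nuclear genes, axis from 0) per class in each library, with 2 control and 2 Wnk1_KO points and a bar for each group mean ± SD. In round spermatid-like cells the means were 1.64% and 3.38%, and in differentiating spermatogonia-like cells 1.86% and 2.01%.

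**Figure D4:**
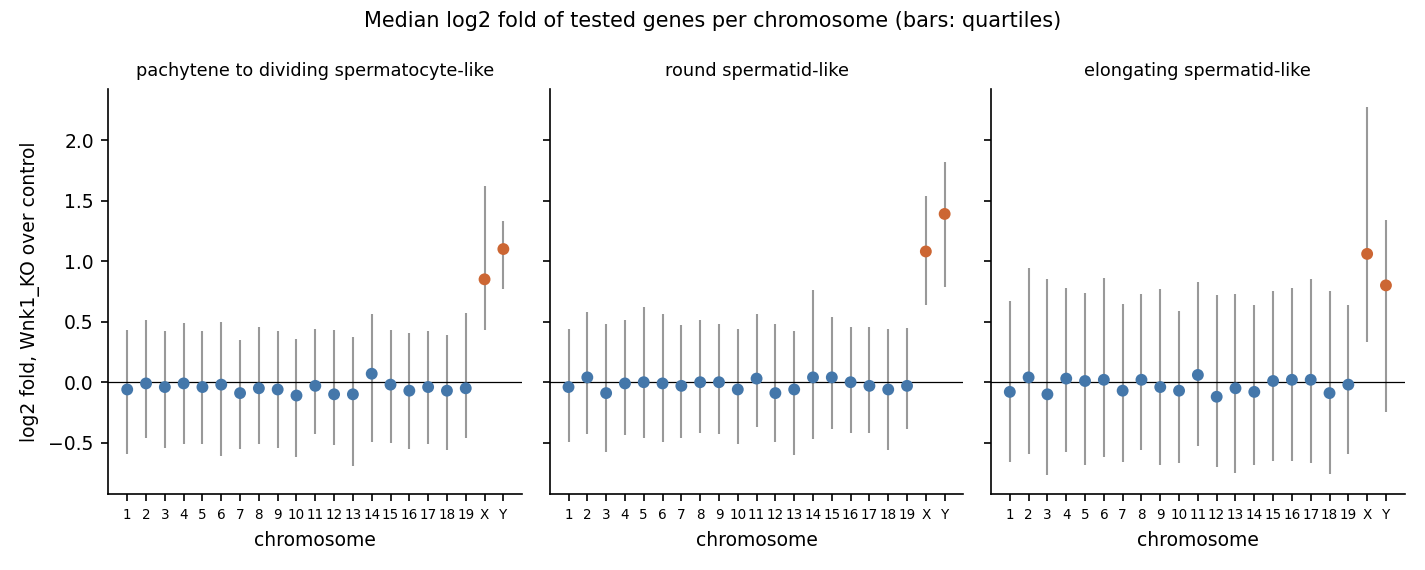
Median log2 fold change of Wnk1_KO over control of the tested genes on each of the 19 autosomes and the X and Y chromosomes, in the 3 late classes, with quartiles as lines. The X chromosome stands at 0.85 in pachytene-to-dividing, 1.08 in round and 1.06 in elongating cells.

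The mitochondrial share differed between the groups over all cells, as did the make-up of the libraries. The median mitochondrial share of a cell was 0.591% and 0.898% in control replicates 1 and 2, and 5.1% and 8.56% in Wnk1_KO replicates 1 and 2 (exact permutation p = 0.33). Elongating spermatid-like cells held little mitochondrial RNA, with medians of 0.0273% to 0.161%. In round spermatid-like cells the libraries overlapped, at 0.252% and 1.07% in control replicates 1 and 2 and 0.077% and 2.6% in Wnk1_KO replicates 1 and 2. Within the 3 early classes the libraries overlapped, with log2 ratios of 0.20, 0.30 and 0.22. These classes, more common in Wnk1_KO libraries, held high shares in both groups. In differentiating spermatogonia-like cells the medians were 4.19% and 7.09% in control and 5.01% and 7.95% in Wnk1_KO replicates 1 and 2. The difference over all cells thus goes with the make-up and is no measure of RNA quality by itself. In pachytene-to-dividing spermatocyte-like cells control replicate 2 stood apart at 9.86%, against 0.851% in control replicate 1 and 1.09% and 2.26% in Wnk1_KO replicates 1 and 2. In elongating spermatid-like cells both Wnk1_KO medians were higher (0.0487% and 0.161%) than both controls (0.0273% and 0.0375%), and without Wnk1_KO replicate 2 the log2 ratio was 0.59 in place of 1.69. UMIs per cell overlapped between the groups in all classes but pachytene-to-dividing.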

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

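All tests of the fall of spermatid genes in early cells were chosen after the result was seen. In differentiating spermatogonia-like, preleptotene-like and leptotene and zygotene-like cells, 1754, 1395 and 1570 genes such as Prm2 fell, by median log2 folds of -1.82, -2.13 and -2.22. Free RNA of spermatids in the droplets would lower the same genes in cells that never make them, and would do so because the Wnk1_KO libraries held fewer spermatids. The same 3 sets of genes had medians of -2.19, -2.23 and -2.17 in stroma-like cells and -2.23, -2.26 and -2.22 in macrophage-like cells, which is in line with free RNA. Loss of Wnk1 inside the early germ cells would need a further fall there, but the median difference from stroma-like cells was 0.25, 0.08 and -0.10, which counts against it as the whole cause.

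For the X chromosome, 1 of the 4 tests, the one without the 5 X-linked genes with the most counts, was chosen before its result was seen and the other 3 after. X-linked genes rose more in the 3 late classes than in differentiating spermatogonia-like cells, with adjusted p of 4.03e-10, 1.15e-07 and 1.89e-07 from the test of the difference between classes; Y-linked genes gave 5.92e-05 in pachytene-to-dividing and 5.92e-05 in round spermatid-like cells, but 0.284 in elongating ones. None held with an estimated correlation (0.215, 0.0777 and 0.0777 for X-linked genes, 0.215 and 0.215 for Y-linked genes). The power of that setting with 4 libraries was not measured, so this loss neither upholds nor rules out the difference. Free RNA of other cells and a few strong genes would each remove the pattern, but at least 93.6% of the log2 ratio was kept without free-RNA genes and at least 102% without the 5 genes, against both.

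Another mix of stages inside a class would leave little change within clusters. Of 14 round and elongating spermatid-like clusters only 4 had the cells in every library for a ratio; these kept at least 81.4% of the class log2 ratio, and the others, most of the control spermatids among them, have no value. Control cells were measured in all 14, and the highest control cluster held 1.94% X-linked counts against 2.94% in the lowest Wnk1_KO class. No mix of the control clusters reaches that level, which speaks against this explanation there. In pachytene-to-dividing clusters as little as 46.4% was kept, in 1 of 4 clusters, and a control cluster at 1.15% exceeded the lowest Wnk1_KO class at 0.964%, so the test cannot tell. That cluster, 19, held 0.244% and 0.334% X-linked counts in control replicates 1 and 2, the latter from 22 cells. It held 0.376% and 0.341% in Wnk1_KO replicates 1 and 2, so its libraries barely differed. Clusters 4, 7 and 13 had log2 ratios of 0.58, 0.96 and 0.53, against 0.31 in cluster 19. Weaker silencing along the whole chromosome would raise X-linked genes everywhere, and 100% of the 20 Mb segments lay above the autosomal median in each late class; with 83.9% or more of X-linked genes positive this nearly had to be so, and the test cannot tell. Sertoli-like and macrophage-like cells, which undergo no meiotic silencing, had X-linked log2 ratios of 0.93 and 0.46 as well, against 0.67 in the pachytene-to-dividing class. Their Y-linked log2 ratios were 0.07 and -0.28, with overlapping libraries, against 0.97 in that class. The Y-linked values of these somatic cells rested on 52 to 167 UMIs per library. Free RNA differed between the groups in these cells. Spermatid tracer genes were at 20427.1 and 24219.6 CPM in control and 2264.5 and 3612.3 CPM in Wnk1_KO Sertoli-like cells. In macrophage-like cells they were at 6205.6 and 9517.8 CPM in control and 868.7 and 1093.6 CPM in Wnk1_KO libraries. Such RNA could lower the X-linked share of these control cells, which was not tested. Part of the rise may have another cause, but these cells cannot tell.

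All tests of the chromosome 6 run were chosen after the result was seen, and 2 of them replaced first forms. The first test of free RNA compared a gene's log2 fold in its highest class with its whole-library fold, and the smallest ratio was 39.9%. The first test of a flank counted both directions, although 315 genes were lower by over 0.5 log2 in all 6 classes and only 23 higher. It found 2% of the genes within 5 Mb of Wnk1 moved in this way, against 3.98% elsewhere. A flank of the Wnk1 locus carried along with the deletion could hold the run, and 0 of 50 genes within 5 Mb of Wnk1 were higher by over 0.5 log2 in all 6 classes. Only 0.108 would be expected from the 18 of 8345 such genes elsewhere, so the test cannot tell. Free RNA set at most 7.44% of the level of Chchd4, Lsm3 and their 3 neighbours in the class where each was highest, where the smallest log2 fold was 1.07, also against that cause. Extra copies or an inserted segment in the Wnk1_KO libraries could raise the run in somatic cells too. Of 15 gene and somatic class pairs 73.3% were higher in both Wnk1_KO libraries, where chance gives 16.7% for a pair. The pairs share the same libraries, and some rest on few UMIs, as Tmem43 in Sertoli-like cells (0 and 0 in control, 2 and 1 in Wnk1_KO replicates 1 and 2). The next genes were so separated as well, Iqsec1 in stroma-like and Slc6a6 in macrophage-like cells. This cannot tell, since not every pair was higher and free RNA was not examined for the run in somatic cells. Sequence of the locus would be needed.

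Barcodes that the filters removed differed between the groups, a signal outside the comparisons above: 11.1% of Wnk1_KO replicate 1 and 18.4% of Wnk1_KO replicate 2 were removed, against 1.11% and 4.51% of control replicates 1 and 2. Hemoglobin genes, which no germ cell should express, were at 3690 CPM in Wnk1_KO replicate 1 and 16.1 CPM in Wnk1_KO replicate 2 over all barcodes, against 0.338 and 0.411 CPM in control replicates 1 and 2.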

How the results depend on the processing

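Over 926 alternatives, 673 gave the same result, 140 were weaker, 17 stronger, 88 moved a value and 8 turned its direction; the cause was not tested unless said. Without free-RNA genes, the adjustment over other genes, single clusters, thinned X-linked shares and the 2 added definitions of post-meiotic cells were chosen after seeing the data. A left-out library leaves its group with 1 sample, which is assumed to vary like the other group. Lists with fewer than 5 members left and clusters under 50 cells in a library gave no value. Every alternative set beforehand was run, but Wnk1 was not among the tested genes in 1 class with thinned cells and in 2 without free-RNA genes.

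Replicate numbers are shared by the 2 groups, but the labels do not say that they stand for a batch. The check of this pairing, the correlation of same-numbered differences, was 0.596 over all cells and from 0.439 to 0.7 in the classes. With a replicate block edgeR called 13975 genes over all cells in place of 4912, 4047 in differentiating spermatogonia-like, 3086 in preleptotene-like, 2736 in leptotene and zygotene-like, 6262 in pachytene-to-dividing, 2642 in round and 4787 in elongating cells. The replicate block in the edgeR test of cells per class gave log2 ratios of 2.5 for differentiating and 1.66 for undifferentiated spermatogonia-like cells, 2.32 for preleptotene-like, 2.24 for leptotene and zygotene-like, -2.27 for round, -2.78 for elongating and -2.38 for post-meiotic cells, all past 0.05. Endothelial-like (3.11; adjusted p = 0.0221) and peritubular myoid-like cells (1.66; 0.0351) passed in edgeR with the block and not without it, and T and NK lymphocyte-like cells (4.74; 0.0351) passed with both. Pachytene-to-dividing cells with the block did not pass among all kept cells (-0.9; edgeR adjusted p = 0.0776). Among germ cells alone they passed with it (-0.8; edgeR adjusted p = 0.00113) and not without it (0.229). Wnk1 passed with it in 4 classes (log2 fold -0.47, -0.43, -0.49 and -0.85 from differentiating spermatogonia-like to pachytene-to-dividing cells).

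With no filter on low counts 8601 genes were called over all cells, 3106 in elongating, 2489 in pachytene-to-dividing and 284 in round cells, and Wnk1 in elongating cells was at -0.05 in place of 0.21. DESeq2 called 8659 genes over all cells, 1491 in pachytene-to-dividing and 102 in round cells. Thinning to 2000 UMIs left 780, 762 and 781 genes in the 3 early classes in order of stage and 134 in elongating cells. With doublets kept 1034 genes were called in elongating cells and Wnk1 was at -0.20 there. At Leiden resolution 2 edgeR called 0 genes in elongating cells (3134 at an unadjusted p under 0.05; DESeq2 737). Without free-RNA genes edgeR called 0 genes in differentiating spermatogonia-like, preleptotene-like, leptotene and zygotene-like and elongating cells (194, 178, 202 and 989 at an unadjusted p under 0.05; DESeq2 1, 0, 0 and 227). Of the genes called before, 7, 10, 20 and 323 stayed in the fit, all with the same sign and an unadjusted p under 0.05, and their median log2 fold went from 1.97, 1.58, 1.57 and 2.10 to 1.97, 1.39, 1.38 and 2.14 in size (median SE from 0.44, 0.38, 0.35 and 0.48 to 0.39, 0.38, 0.37 and 0.47). With the p of the first fit adjusted over genes that are not free-RNA genes, edgeR called 0, 0, 0 and 30, so in the 3 early classes the adjustment alone ended the calls of the genes that stayed. Cluster 15 alone gave 756 genes among elongating and cluster 7 alone 789 among pachytene-to-dividing cells.

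The edgeR test of cells per class gave 2.5 for differentiating and 1.66 for undifferentiated spermatogonia-like cells, 2.3 for preleptotene-like, 2.24 for leptotene and zygotene-like, -2.81 for elongating and -2.36 for post-meiotic cells. With a minimum of 200 genes and no other filter the log2 ratio of differentiating spermatogonia-like cells was 2.36 and of leptotene and zygotene-like cells 2.02. The X-linked log2 ratio without free-RNA genes was 0.08, 0.10 and 0.16 in the 3 early classes, 0.30 in preleptotene-like cells with doublets kept, and 1.30 in elongating cells thinned to 2000 UMIs.

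With an estimated correlation camera called 0 lists in each of the 7 comparisons, so this setting does not tell lists apart. Fry called 0 over all cells and in pachytene-to-dividing, round and elongating cells, 2 in leptotene and zygotene-like cells, and 4 each in differentiating spermatogonia-like and preleptotene-like cells, where camera called 5 and 6. Without free-RNA genes 0 lists were called in differentiating spermatogonia-like and preleptotene-like cells, 1 in leptotene and zygotene-like, 4 in pachytene-to-dividing, 2 in round and 1 in elongating cells, and the metabolism list turned direction in the 3 early classes (camera adjusted p = 0.919, 0.834 and 0.268).

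Leaving out each library in turn gave 613 to 7975 genes over all cells, 729 to 2226 in elongating, 798 to 1289 in pachytene-to-dividing and 0 to 13 in round cells (edgeR; with 0 called without Wnk1_KO replicate 1, 2702 were at an unadjusted p under 0.05 and DESeq2 called 59 and 76). Wnk1 ranged from -0.52 to 0.78 in elongating and from -1.93 to 1.82 in round cells. Log2 ratios of shares ranged from -1.91 to 0.91 for Sertoli-like, -0.19 to 2.70 for stroma-like, 0.88 to 1.69 for macrophage-like, 2.38 to 2.62 for differentiating spermatogonia-like, 2.09 to 2.55 for preleptotene-like, -1.43 to -0.28 for pachytene-to-dividing, -3.03 to -1.60 for round and -3.13 to -2.40 for elongating cells. The X-linked ratio ranged from 0.37 to 1.06 in pachytene-to-dividing and 0.92 to 1.15 in round cells. The ratio of UMIs per cell ranged from 0.06 to 0.87 over all cells, 0.25 to 3.10 in pachytene-to-dividing, -0.73 to 1.43 in round and 0.04 to 1.09 in elongating cells. That of the mitochondrial share ranged from -2.55 to 0.98, -3.10 to 2.41 and 0.59 to 2.31 in the last 3 classes. The lists called ranged from 5 to 10 in pachytene-to-dividing, 4 to 10 in preleptotene-like and 3 to 7 in round cells.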

Other observations

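Some genes of other programmes were counted higher in the few elongating spermatid-like cells of the Wnk1_KO libraries, and free RNA may account for part of them. Of 19 spermatogenic transcription regulators 6 rose and 2 fell (6 and 3 adjusted over the list alone), among them Sohlh1, a regulator of spermatogonia, from 5.02 ± 1.63 to 24.4 ± 7.99 CPM (SD, n = 2 each) and Stra8 from 0.602 ± 0.338 to 17.4 ± 0.868 CPM. Of 9 Sertoli genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with Cst12, a cystatin, from 2.99 ± 2.12 to 24.5 ± 16 CPM. Camera called neither list (adjusted p = 0.183 and 0.0589), and 13 of the 19 and 5 of the 9 members were free-RNA genes. Without free-RNA genes edgeR called 0 genes in this class, while 989 had an unadjusted p under 0.05. In the group where it was larger, the free-RNA estimate was 100% of the level of Stra8, 17.6% of Cst12 and 16.5% of Sohlh1.

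Under the loosest filter the removed barcodes of Wnk1_KO replicate 2 held 269 pachytene-to-dividing spermatocyte-like and 51 round spermatid-like cells, against 7 and 9 in Wnk1_KO replicate 1, 0 and 0 in control replicate 1 and 24 and 5 in control replicate 2. Most removed barcodes of Wnk1_KO replicate 2 stayed unnamed, at 999. Unnamed ones numbered 181 in Wnk1_KO replicate 1, and 30 and 192 in control replicates 1 and 2. Removed Sertoli-like cells numbered 34 and 70 in control replicates 1 and 2 and 165 and 112 in Wnk1_KO replicates 1 and 2, and all 14 erythroid-like cells came from Wnk1_KO replicate 1. In Sertoli-like cells the X-linked share was 2.66% ± 0.461 in control and 5.05% ± 1.04 in Wnk1_KO libraries (SD, n = 2 each), while the free-RNA estimate for this class was 59.03% and 34.78% of the whole-library level in control replicates 1 and 2 and 18.26% and 36.25% in Wnk1_KO replicates 1 and 2.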
